A study of Homo sapiens and Mus musculus with 30 samples.

How the data were processed

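Polysome RNA and total RNA were measured in HEK293A and NIH3T3 cells at 5 levels of LIN28B, and small RNA in HEK293A. Per the labels, cells grew in DMEM with 10% FBS, the LIN28B transgene was switched on with doxycycline at 10 ng/ml, and let-7a was brought in at 10 nM with Lipofectamine RNAiMAX. RNA was taken up in Trizol and small RNA with miRvana, Illumina kits for polyA-selected RNA and for small RNA made the libraries, and AGO2 was precipitated with an antibody against it. The series design speaks of 2 replicates for each condition, yet each table holds 1 column per level and fraction, and whether replicates were pooled is not given. Binding-site data of the series were not used here.

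RPKM values were deposited for the polysome and total RNA libraries, that is reads per kilobase of gene and per 1e6 reads as counted by the authors, in 1 table for HEK293A (11342 genes), 1 for NIH3T3 (41128 genes) and 1 for the let-7a libraries (57820 genes). The deposited human table lists only genes at 1 RPKM or more in all 5 total RNA libraries. Raw counts per Ensembl gene were deposited for the 8 small RNA libraries. Per the submitters' processing notes cutadapt, STAR and the builds hg19 and mm10 were used. The column headers of the small RNA table name polyA trimming, adapter trimming, reads left unmapped by a first mapping, and bowtie. The roles of the other tools, the counting tool, its strand setting and the annotation release are not given in the sources used here.

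Low RPKM values fall on whole-number steps for each gene and library, from which reads were recovered within a tolerance of 0.02 of a whole number. This held for 99.99% of HEK293A genes (11341 of 11342) and 21037 of the 21042 NIH3T3 genes above 0. In each let-7a library it held for 99.9% of those genes above 0 that the human table also lists. Other genes of the let-7a libraries were not recovered. Recovered reads gave the depths, the counting error and an alternative count test.

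Ribosome occupancy was the log2 of polysome RPKM plus 0.5 minus the log2 of total RPKM plus 0.5, over genes with a mean of at least 1 RPKM. A straight line over the rank of the level, from 0 to 4, was fitted to occupancy and to log2 total RNA with limma. Moderated variances followed the mean of the values fitted, which for occupancy is the mean log2 ratio and not the expression level. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The shared level ranks and 5 libraries leave few degrees of freedom per gene. Gene lists, 30 of them, were fixed by name before the data were examined, as were the comparisons, the rule for named genes and the alternatives, apart from those given in the closing section as added later. The lists with at least 5 measured members, 23 in HEK293A and 22 in NIH3T3, were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The cell lines were compared over shared gene symbols, with a term for the difference in slope.

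The let-7a libraries were compared with untransfected X0 as differences without a test. Each list's median was set against 10000 random lists drawn to match its members' expression. Small RNA counts were tested with edgeR's quasi-likelihood test, with TMM normalization, edgeR's filter on low counts and additive terms for LIN28B, let-7 and fraction, and again with DESeq2. MicroRNA features were those whose symbols name a microRNA. All 57820 identifiers were paired with symbols through the deposited let-7a table. A RefSeq annotation was used only for gene names, neighbours and overlaps. Shares carry exact binomial (Clopper-Pearson) intervals at 95%, and the limit for a count of 0 is 3 counts.

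Genes were named by rule: LIN28B and LIN28A, then for each trend the 5 largest rises and falls past the threshold at a mean of at least 5 RPKM, or the 5 of smallest p where fewer passed. Up to 4 members of smallest p in each called list, and HMGA2, the IGF2BP genes, CCNB1, CDK4, IGF2 and DICER1 where measured, were added. For small RNA the rule took let-7 features at a mean of at least 10 counts and the 5 largest rises and falls at a mean of at least 50 counts. LIN28A and IGF2 are not in the human table.

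The methods were tested on simulated data. Among 11116 simulated HEK293A genes, limma recovered 32.3% of 99 genes given a slope of 0.25 and 90.0% of 100 given 0.5, with 11 false calls (8.27% of calls). In NIH3T3 it recovered 18.4% and 94.8%, with 10 false calls (8.33%). The count test recovered 45.5% and 93.0% in HEK293A (9 false calls, 6.12%) and 55.1% and 95.9% in NIH3T3 (6 false calls, 3.92%). Both false shares from limma, and that of the count test in HEK293A, exceed the 5% aimed at. A list moved by design was called in each line and 0 of 10 others were. The simulated genes were drawn independently of each other, so these rates do not cover differences shared by many genes of a library. For small RNA 12 of 12 features changed 4-fold were recovered, with 1 false call. All of these simulations fixed the spread between libraries in advance rather than estimating it from these data. The recovered shares may therefore not hold for the real libraries, and they do not show that a lack of calls means a lack of change.

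Alternatives covered the pseudocount, the filter on low values, centring on the trimmed mean (0.3 trimmed), quantile normalization, X0 against the other levels, the measured LIN28B value as covariate, the count test, and leaving out each library. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.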

Results

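A set of 30 sequencing libraries was analysed from cells carrying graded amounts of LIN28B, an RNA-binding protein that blocks the maturation of let-7 microRNAs and binds many messenger RNAs. HEK293A, a human embryonic kidney line, and NIH3T3, a mouse embryonic fibroblast line, were each set at 5 levels of LIN28B, from X0, the lowest, to X4, the highest. X0 is taken as the knockout in HEK293A, while the NIH3T3 titles name no knockout. Each level had 1 library of total RNA and 1 library of polysome RNA, which is RNA bound by ribosomes, so that no level had a replicate of its own. HEK293A X0 cells transfected with mature let-7a gave 2 further libraries, 1 of each fraction. Another 8 libraries held small RNA from HEK293A, taken from the knockout and from X3, with and without let-7 transfection, as total small RNA and as small RNA bound by AGO2, the Argonaute protein that carries microRNAs. The HEK293A total RNA libraries held 37.6 to 55.9 M recovered reads (M, 1e6) and the polysome libraries 9.04 to 14.5 M. In NIH3T3 these numbers were 15.1 to 23.5 M and 15.5 to 20.3 M. Over the genes of the human table, the let-7a pair held 35.1 M recovered reads in total RNA and 7.38 M in polysome RNA. The small RNA libraries held 73083 to 172995 counts. The p-values below measure only the spread between these samples, which may be technical, and each trend p rests on a straight line over the rank of the level.

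LIN28B itself followed the labels. In HEK293A its total RNA stood at 3.60 RPKM at X0, 23.0 at X1, 33.4 at X2, 81.2 at X3 and 208 at X4, a 57.8-fold range, resting on 799 reads at X0 and 49549 at X4. Its polysome RNA went from 1.85 RPKM at X0 through 12.4, 12.9 and 22.3 to 39.8 at X4. The knockout therefore still held LIN28B reads in both fractions. In NIH3T3 the mouse gene Lin28b had 1, 1, 1, 9 and 42 total RNA reads from X0 to X4, and 1, 3, 4, 13 and 42 polysome reads. Its paralog Lin28a had 5, 3, 3, 0 and 1 total RNA reads. Whether the NIH3T3 transgene is of human or mouse sequence is not given in the sources used here, so these low counts do not measure it.

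The first question was whether the share of each messenger RNA found on ribosomes changed as LIN28B rose. Ribosome occupancy, the log2 ratio of polysome to total RNA, lay further from X0 in the X3 and X4 libraries of HEK293A than in those of X1 and X2. Across 11125 genes the SD of the change from X0 was 0.39 at X1, 0.33 at X2, 0.67 at X3 and 0.81 at X4, and 1.12%, 0.593%, 14.2% and 29.3% of genes differed by more than 1 log2 unit. The SD at X4 was 2.05 times that at X1 (95% interval from resampled genes 2.03 to 2.08). Counting error alone gave an SD of 0.11 to 0.12 for the gene of median counting variance. It is larger for genes with fewer reads, so these values are not the SD that counting would give across all genes. With 1 library per level, neither the interval over genes nor the counting error measures how far libraries vary, so this order has no test. The polysome libraries spread more than the total RNA libraries, with an SD of 0.89 against 0.26 at X4. NIH3T3 did not show this order, with SDs of 0.45, 0.58, 0.61 and 0.46 over 10952 genes and a ratio of X4 to X1 of 1.02 (0.990 to 1.05). All of these differences share the X0 libraries. The human table lists only genes at 1 RPKM or more in each of the 5 total RNA libraries, so a gene lost from total RNA at any level is not in it.

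**Figure D1:**
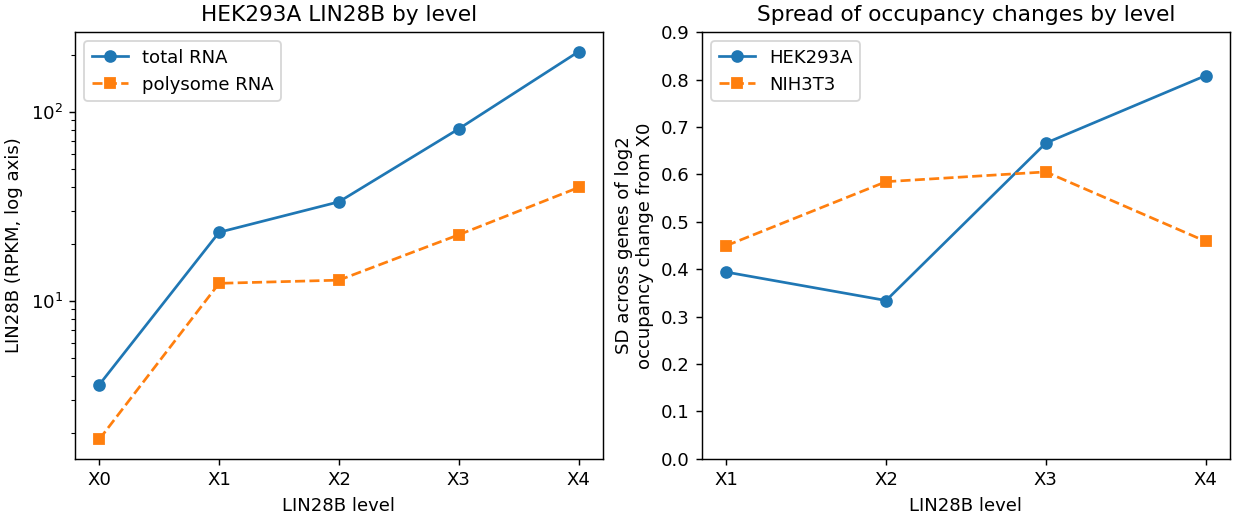
Left, LIN28B RPKM (log axis) in the HEK293A total RNA and polysome libraries of each level, 1 library per point; right, the SD across genes of the log2 occupancy change from X0 in both cell lines. LIN28B total RNA runs from 3.60 to 208 RPKM, and the HEK293A spread reaches 0.81 at X4 while that of NIH3T3 is 0.46.

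In HEK293A occupancy rose most for EEF1E1, a scaffold of the aminoacyl-tRNA synthetase complex, which gained 0.50 ± 0.14 log2 units per level (SE; adjusted p = 0.0139, limma) and was 5.58-fold higher at X4 than at X0. Its polysome RNA went from 8.44 to 49.5 RPKM while its total RNA was 14.5 RPKM at both ends. KIF20B, a mitotic kinesin (4.18-fold), ESF1, a nucleolar factor in ribosomal RNA processing (3.35-fold), ITGB3BP, a centromere protein (4.52-fold), and the zinc finger gene ZNF92 (4.91-fold) rose as well, with adjusted p from 0.00346 to 0.0195. HIST1H2BJ, a histone H2B gene, lost most, falling by 0.77 per level. Then came RNF208, a RING finger protein (fell by 0.51 per level), the immediate early gene IER2 (fell by 0.46), SURF6, a nucleolar protein (fell by 0.43), and SDF4, a calcium-binding protein of the Golgi (fell by 0.43), each with an adjusted p of 0.00319. LIN28B's own occupancy fell by 0.41 ± 0.06 per level, since its polysome RNA grew less than its total RNA. HIST1H2BJ shares sequence with other H2B genes, and its RNA rose along with that of LIN28B in both fractions, so it is uncertain. Without X4 0 of these genes passed.

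Over all genes, 6465 of 11125 changed in occupancy, 2124 upward and 4341 downward. The median gene moved by −0.07 log2 units per level and stood at −0.32 at X4 relative to X0. With each library centred on its trimmed mean the split was 3218 up and 2962 down, so that the upward share went from 32.9% to 52.1%. Quantile normalization gave 2914 up and 2960 down (49.6%), and the count test on recovered reads 3289 up and 3198 down. The list tests below therefore compare members with all other genes, while slopes and counts of members are not set relative to them. The number of calls rested on the ends of the series, with 0 genes passing without X4 (1372 up and 3120 down at an unadjusted p under 0.05), 1674 without X0, and 2 when X0 was set against the other levels as a group.

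**Figure D2:**
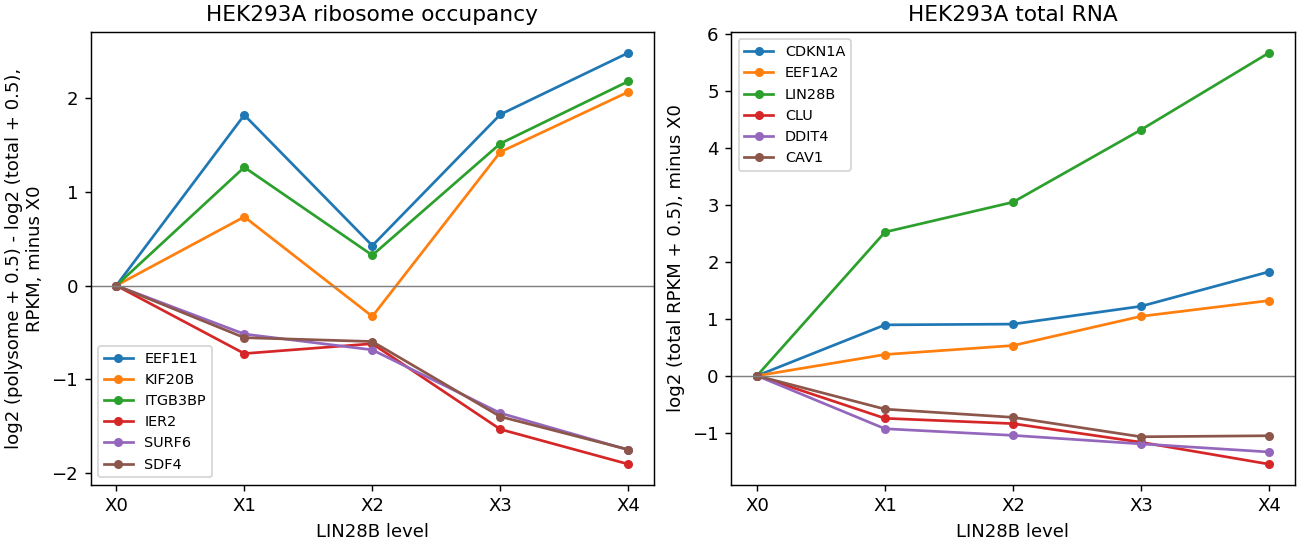
Log2 occupancy (left) and log2 total RNA (right) of 6 genes each by LIN28B level in HEK293A, set to 0 at X0, on the log2(RPKM + 0.5) scale, 1 library per point. EEF1E1 and ITGB3BP were higher at X1 than at X2 before reaching 5.58-fold and 4.52-fold at X4, whereas SURF6 and SDF4 were lower at each level above X0.

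The 75 measured cytosolic ribosomal proteins gained occupancy relative to other genes. Of these, 36 rose and 5 fell (35 and 5 adjusted over the list alone; 54 and 3 after centring), with camera's adjusted p = 2.67e-07 and adjusted p = 0.736 with an estimated correlation. RPL31 rose by 0.24 ± 0.05 per level, while RPL8 fell by 0.34, RPL13 fell by 0.31 and RPS2 fell by 0.25. Nuclear-encoded subunits of the respiratory chain also gained, with 30 of 71 up and 15 down (31 and 15 adjusted over the list alone; 42 and 7 after centring; adjusted p = 0.000223, and adjusted p = 0.736 with an estimated correlation). NDUFA4 of the respiratory chain rose by 0.18, and the complex I subunit NDUFV1 (fell by 0.35), the ATP synthase subunit ATP5D (fell by 0.35) and the succinate dehydrogenase subunit SDHA (fell by 0.30) went the other way. The mitotic list held 14 risers, among them CCNB1 (0.16 ± 0.05, adjusted p = 0.0138), and 6 genes that fell, out of 31 (16 and 7 adjusted over the list alone; 18 and 6 after centring; adjusted p = 0.021, and adjusted p = 0.736 with an estimated correlation). Its 4 members of smallest p all fell, namely the mitotic kinases PLK1 (fell by 0.38) and AURKB (fell by 0.28), the anaphase activator CDC20 (fell by 0.38) and survivin, BIRC5 (fell by 0.31). Ribosomal proteins and histones have many near-identical copies, so single members are uncertain.

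The proteasome list had 12 of 30 members up and 4 down, both counts the same adjusted over the list alone (15 and 3 after centring; adjusted p = 0.0351, and adjusted p = 0.736 with an estimated correlation). The core subunits PSMA3 (0.25) and PSMA4 (0.27) rose, and the regulatory subunits PSMD3 (fell by 0.38) and PSMD2 (fell by 0.30) did not. Mitochondrial ribosomal proteins divided evenly, 22 up and 21 down of 72 (23 and 21 adjusted over the list alone; 36 and 15 after centring), with a test in favour of a gain relative to other genes (adjusted p = 0.0409, and adjusted p = 0.757 with an estimated correlation). MRPL42 rose by 0.34, and MRPS2 fell by 0.40, MRPS26 fell by 0.32 and MRPL10 fell by 0.30. Cell-surface and secreted proteins lost occupancy. Of 61 measured, 43 fell and 3 rose, also when adjusted over the list alone (34 and 5 after centring), with a median slope of −0.23, adjusted p = 0.000493 and adjusted p = 0.736 with an estimated correlation. The largest falls by p were those of BSG, or basigin (fell by 0.39 per level), the heparan sulfate proteoglycan SDC1 (fell by 0.37), the receptor phosphatase PTPRF (fell by 0.36) and the endocytic receptor LRP1 (fell by 0.34). The polysome RNA of LRP1 was 0.392 RPKM at X0 and 0.371 at X4, below the 0.5 added before the log2. Its total RNA rose from 1.26 to 4.14 RPKM, so its fall rests on total RNA. The proteasome call was lost without X1 (adjusted p = 0.065) and X3 (0.0666), that of the mitochondrial ribosome without X1 (0.114) and X3 (0.079), and quantile normalization ended those of the proteasome (0.498), mitochondrial ribosome (0.498), respiratory chain (0.117) and mitotic genes (0.207).

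**Figure D3:**
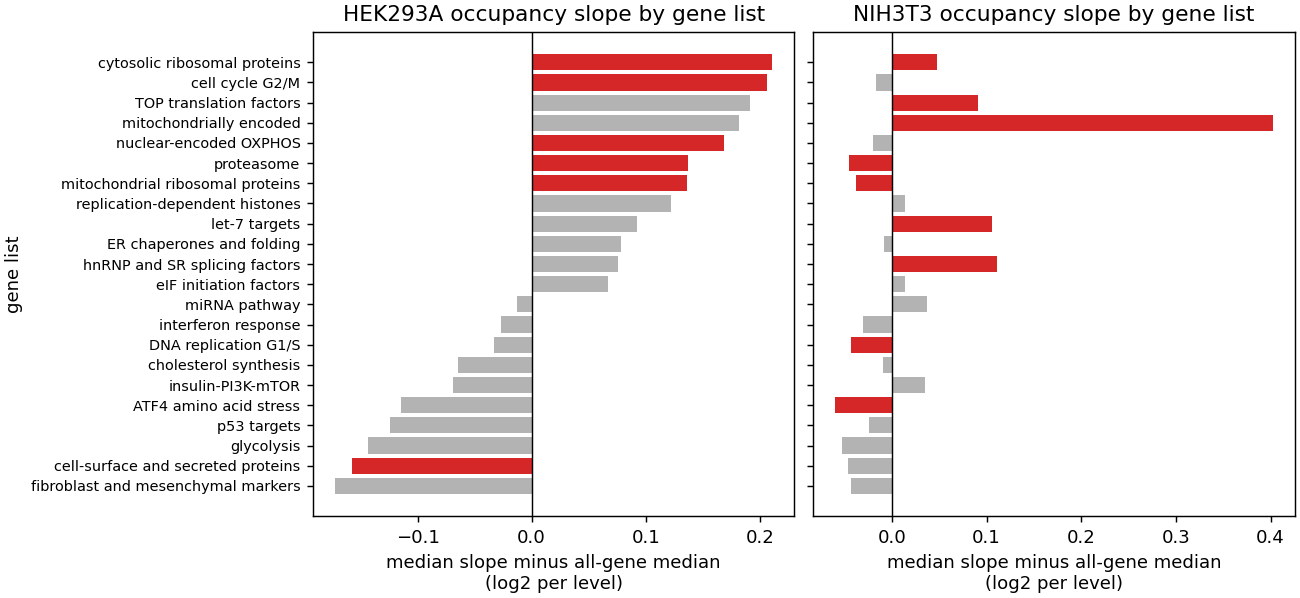
Median occupancy slope of each gene list minus the median of all genes, in log2 units per level, for HEK293A (left) and NIH3T3 (right); the 22 lists measured in both are drawn, those with a camera adjusted p under 0.05 in red and the others in grey. Cytosolic ribosomal proteins lie at 0.21 in HEK293A, and mitochondrially encoded genes at 0.40 in NIH3T3.

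Among genes bound or regulated in the LIN28 and let-7 literature, occupancy moved both ways. IGF2BP1 (−0.22, adjusted p = 0.00967) and IGF2BP2 (−0.21, adjusted p = 0.0083), RNA-binding proteins and let-7 targets, fell in occupancy. IGF2BP3 (0.14, adjusted p = 0.045) and DICER1, the enzyme that cuts microRNA precursors (0.16, adjusted p = 0.0349), rose. HMGA2, a chromatin protein, had a slope of 0.02 (adjusted p = 0.852) and the cyclin-dependent kinase CDK4 −0.06 (adjusted p = 0.262; 0.00 after centring). The 53 let-7 targets held 16 risers and 16 that fell (16 and 18 adjusted over the list alone; 20 and 11 after centring), and camera did not call the list (adjusted p = 0.264). Its median slope was 0.02 and its mean −0.000106, so median and mean differed in sign.

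Total RNA changed in fewer HEK293A genes, 168 upward and 86 downward, 254 of 11342. Beyond LIN28B (1.31 ± 0.09 log2 units per level, adjusted p = 0.00087), the largest rise was that of HIST1H2BJ, from 2.12 to 365 RPKM. Its total RNA rose along with that of LIN28B, at 36.4, 56.3, 159 and 365 RPKM from X1 to X4 beside 23.0, 33.4, 81.2 and 208. Whether these reads come from its own gene was not tested. CDKN1A, the p53-induced cell cycle inhibitor p21, went from 6.88 to 25.6 RPKM (0.40 ± 0.05, adjusted p = 0.00793), the elongation factor EEF1A2 from 65.0 to 163 RPKM and the troponin gene TNNT1 from 5.35 to 14.7. The secreted chaperone clusterin, CLU, fell by 0.35 ± 0.04 per level (189 to 64.0 RPKM, adjusted p = 0.00477). GPRC5A, a retinoic acid-induced receptor, DDIT4, an mTOR inhibitor, the nuclear noncoding RNA MALAT1 and the caveola protein CAV1 fell by 0.33, 0.29, 0.29 and 0.26 per level, with adjusted p of 0.0366, 0.0365, 0.00976 and 0.0172. After centring GPRC5A (0.0602) and DDIT4 (0.0606) no longer passed. HIST1H2BJ and EEF1A2 share sequence with paralogs and are uncertain. The number of calls fell to 3 without X0 and 119 without X3, and reached 544 without X4. The 3 genes left without X0 were HIST1H2BJ, LIN28B and EEF1A2. The count was 159 after centring (97 up and 62 down), 117 over genes at a mean of 5 RPKM or more, and 3 with X0 set against the other levels.

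Known let-7 targets rose in total RNA as a list, with 9 of 53 members up and 0 down (20 up and 1 down adjusted over the list alone; 3 up and 0 down after centring; adjusted p = 5.19e-09, and adjusted p = 0.533 with an estimated correlation). LIN28B is not in this list. The transcription factors ARID3B (2.48-fold from X0 to X4), NR6A1 (2.32-fold) and ARID3A (1.92-fold), the hyaluronidase TMEM2 (1.82-fold) and IGF2BP1 (2.04-fold, adjusted p = 0.0309) were among them, and after centring ARID3B (0.0596) and IGF2BP1 (0.0598) no longer passed. HMGA2 (0.34 ± 0.10 per level, adjusted p = 0.105), DICER1 (0.16, adjusted p = 0.0563) and IGF2BP2 (0.09, adjusted p = 0.0608) rose without passing the test. HMGA2 stood at 5.87 RPKM at X0 and at 16.7, 18.5, 19.7 and 18.8 from X1 to X4. IGF2BP1, ARID3B and NR6A1 also moved more from X0 to X1 than from X1 to X4 in log2, while ARID3A and TMEM2 did not. The X0 side of this step is 1 library, and the labels do not say whether it received doxycycline. IGF2BP3 (0.02), CCNB1 (−0.03) and CDK4 (−0.05) had adjusted p of 0.756, 0.446 and 0.261. Targets of p53 rose as well, 6 of 23 up and 0 down (16 up and 1 down adjusted over the list alone; 2 up and 0 down after centring; adjusted p = 3.41e-09, and adjusted p = 0.423 with an estimated correlation), including CDKN1A, TP53I3 (2.99-fold), BTG2 (1.75-fold) and ZMAT3 (1.62-fold). After centring BTG2 (0.0513) and ZMAT3 (0.0518) no longer passed.

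Genes of cholesterol synthesis fell in total RNA, 5 of 23 down and 1 up (13 down and 2 up adjusted over the list alone; 3 down and 1 up after centring; adjusted p = 1.12e-06, and adjusted p = 0.423 with an estimated correlation). The enzymes SQLE (fell by 0.15 per level), IDI1 (fell by 0.17) and LSS (fell by 0.15) and the sterol sensor INSIG1 (fell by 0.23) led this list, LSS not passing after centring (0.0518). Targets of ATF4, the transcription factor of amino acid stress, fell too, 3 of 28 down and 1 up (8 and 1 adjusted over the list alone; 2 and 0 after centring; adjusted p = 0.000973, and adjusted p = 0.423 with an estimated correlation). Asparagine synthetase, ASNS (fell by 0.19), the cystine transporter SLC7A11 (fell by 0.20) and DDIT4 fell, and the pseudokinase TRIB3 rose by 0.15, while after centring TRIB3 (0.0554) and DDIT4 did not pass. Cytosolic ribosomal proteins were shifted down with 0 of 75 members passing, also adjusted over the list alone (median slope −0.03; adjusted p = 4.24e-06, and adjusted p = 0.423 with an estimated correlation), RPS26 (−0.07) and RPS3 (−0.05) having the smallest p with RPL39 (−0.07) and RPL12 (−0.04). The list called TOP factors here holds genes with a 5′ terminal oligopyrimidine (TOP) tract, translation factors and others. It was lower too (camera's adjusted p = 0.0135, and adjusted p = 0.423 with an estimated correlation). Of its 22 members 1 was down, also adjusted over the list alone, and 0 after centring. That member was the intermediate filament gene VIM, which fell by 0.15 (limma's adjusted p = 0.0347, but 0.0598 after centring and 0.0521 after quantile normalization). The call for the HEK293A total RNA list ATF4 amino acid stress was lost without X4 (adjusted p = 0.0716), and the TOP call without X0 (0.0599) and after quantile normalization (0.0973).

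In HEK293A total RNA 4 other lists shifted upward. Mitochondrially encoded genes had 1 of 13 up, MT-ATP8 (0.10 per level; 1 adjusted over the list alone; 0 after centring, where MT-ATP8 had an adjusted p of 0.0833; adjusted p for the list = 0.0135, and adjusted p = 0.733 with an estimated correlation), and the call was lost without X3 (0.525). The proteasome had 0 of 30 up (0 adjusted over the list alone; adjusted p = 0.0252, and adjusted p = 0.634 with an estimated correlation), PSMD14 coming closest at 0.09 per level, and was lost without X0 (0.339) or X2 (0.062). Interferon response genes had 2 of 11 up, ISG15 (1.54-fold) among them, 2 also adjusted over the list alone (1 after centring, when ISG15 no longer passed at 0.0611, nor with the count test at 0.0981; adjusted p = 0.028, and adjusted p = 0.634 with an estimated correlation), and were lost without X4 (0.767). Cell-surface and secreted proteins had 5 of 62 up and 3 down (11 and 5 adjusted over the list alone; 3 and 3 after centring; adjusted p = 0.0374, and adjusted p = 0.652 with an estimated correlation). LRP1 (2.63-fold), COL18A1 (1.62-fold) and SDC1 (1.51-fold) rose and the semaphorin receptor NRP1 fell by 0.15 per level. This call was lost without X1 (0.238), X2 (0.051) or X3 (0.358).

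In NIH3T3 0 of 10952 genes passed for occupancy with limma, with 294 up and 258 down at an unadjusted p under 0.05 where 548 would arise by chance, and 0 passed with the count test on recovered reads (612 up and 174 down unadjusted). The smallest p upward were those of Tgfbi, a matrix protein, Trappc6b, Ncl, the nucleolar protein nucleolin, Sp140 and Nme2, and downward those of Tnfsf9, Elmod3, Lrp1, Anxa8 and Fam212a, each with an adjusted p of 0.639. Tgfbi stood at 52.0 RPKM of total RNA at X0 and 0.153 at X4, so its occupancy slope of 0.29 ± 0.06 rests on few reads at X4. HMGA2's mouse counterpart Hmga2 had a slope of 0.18 ± 0.12 and Dicer1 one of 0.11 ± 0.06 (adjusted p = 0.639 for both). Without X4 there were 1916 genes up and 832 down at an unadjusted p under 0.05, still with 0 passing.

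Lists nevertheless shifted in NIH3T3 occupancy, 5 up and 4 down of 22, in each of which 0 members passed, also when adjusted over the list alone. All 9 had an adjusted p = 0.672 with an estimated correlation. The list of TOP factors, translation factors and other genes, moved up (median slope 0.08, camera's adjusted p = 7.68e-05). The nucleolar chaperone Npm1 stood at 0.42 ± 0.15 per level, Nap1l1 at 0.38, Eif3e at 0.37 and Hnrnpa1 at 0.23. The separate list of initiation factors was not called (camera's adjusted p = 0.436). The 12 mitochondrially encoded genes moved most (median 0.39, adjusted p = 7.68e-05), with mt-Atp8 at 0.80 ± 0.36, mt-Atp6 at 0.51, mt-Nd4 at 0.46 and mt-Co1 at 0.34. In these 8 genes occupancy did not follow the order of the levels but was highest at X2 or X3 and lower at X4, as for Npm1 (−1.19, 0.19, 0.94, 1.06 and 0.49 from X0 to X4) and mt-Atp8 (−3.41, −5.12, −0.92, −0.35 and −1.79). The let-7 targets (median 0.10, adjusted p = 0.000608; Nap1l1, Igf2bp2, Rdx and Arhgap28), hnRNP and SR splicing factors (median 0.10, adjusted p = 0.00564; Srsf11, Sf3b1 and Mbnl2) and cytosolic ribosomal proteins (median 0.04, adjusted p = 0.00944; Rpl32, Rpl24, Rpl10 and Rpl23) were also higher. Lower were mitochondrial ribosomal proteins (median −0.05, adjusted p = 0.00238; Mrpl22 and Mrps10), ATF4 targets (−0.07, adjusted p = 0.00326; Aars, Slc7a5, Aldh18a1 and Asns), DNA replication genes (−0.05, adjusted p = 0.00845; Mcm2, Cdc45, Mcm7 and Pold1) and the proteasome (−0.06, adjusted p = 0.0282; Psmd2, Psmd3, Psmc4 and Psmb5). Centring ended the calls of cytosolic ribosomal proteins (0.106) and the proteasome (0.0511), and quantile normalization these (0.137 and 0.173) and that of mitochondrial ribosomal proteins (0.137). Without X0 the calls for cytosolic ribosomal proteins (0.674), TOP factors (0.669), ATF4 targets (0.341) and splicing factors (0.0899) were lost; without X1 those for the NIH3T3 occupancy list hnRNP and SR splicing factors (0.0827), mitochondrial ribosomal proteins (0.0638) and the proteasome (0.373). Without X2 the cytosolic ribosomal call was lost (0.116), and without X4 those for cytosolic ribosomal proteins (0.903), DNA replication (0.149), mitochondrial ribosomal proteins (0.129) and the proteasome (0.614).

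In NIH3T3 total RNA no single gene passed the trend, while fibroblast markers and other lists shifted. Of 10348 genes, 0 passed with limma (759 up and 377 down at an unadjusted p under 0.05) or with the count test (691 up and 603 down unadjusted), whereas 2241 differed between X0 and the other levels, 1189 higher and 1052 lower than at X0. The X0 side of that test is 1 library, so a shift of this library alone would give the same calls. The labels give 1 protocol text for all libraries and do not say which received doxycycline, so if X0 did not, X0 against the other levels does not separate LIN28B from the drug. The same limit holds for X0 in HEK293A and for the knockout against X3 in small RNA. Without X0 the trend passed for 22 genes, 10 up and 12 down. The smallest trend p belonged to the basement membrane protein Nid2 (2.44 to 14.96 RPKM, adjusted p = 0.172), Thbs1, Tagln, Tinagl1 and Col5a1 upward and to Stc1, Mir6236, Nrn1, Nr4a2 and Rcan1 downward. Fibroblast and mesenchymal markers were higher as a list, with 14 of 23 up and 2 down adjusted over the list alone and 0 over all genes (median slope 0.19, adjusted p = 6.8e-07, and adjusted p = 0.612 with an estimated correlation). The smooth muscle actin Acta2 ran from 112 to 576 RPKM, Tagln from 18.3 to 84.0, Col1a1 from 159 to 448 and Col5a1 from 15.1 to 48.0. Chaperones of the endoplasmic reticulum, led by Hyou1 (5.23 to 14.6 RPKM), Stt3a, Ddost and Rpn2, had 10 of 35 up adjusted over the list alone and 0 over all genes (adjusted p = 2.81e-09, and adjusted p = 0.612 with an estimated correlation).

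The other NIH3T3 total RNA lists that camera called had 0 members past the all-gene test. Cell-surface and secreted proteins were higher (2 of 49 up adjusted over the list alone; adjusted p = 6.8e-07; Itga5, Plxnb2, Agrn and Slc1a5), as were the proteasome (7 of 31 adjusted over the list alone; adjusted p = 1.25e-05; Psmb5, Psmb3, Psmb2 and Psmb7), the respiratory chain (adjusted p = 2.38e-06; Uqcrc1, Uqcrq, Cox5a and Ndufb8) and mitochondrial ribosomal proteins (adjusted p = 0.000663; Mrpl37, Mrpl46, Mrps18c and Mrps18b), each with an adjusted p = 0.612 with an estimated correlation. DNA replication genes (adjusted p = 0.000663; Mcm2, Mcm3, Ccne1 and Mcm5; adjusted p = 0.754 with an estimated correlation) and mitotic genes (adjusted p = 0.00658; Bub1b, Plk1, Cdc20 and Birc5; adjusted p = 0.833 with an estimated correlation) were higher too. Lower were TOP factors (adjusted p = 8.31e-05; Eif4b, Tpt1, Vim and Pabpc4), mitochondrially encoded genes (adjusted p = 0.000856; mt-Atp8, mt-Atp6, mt-Nd4 and mt-Co2) and p53 targets (adjusted p = 0.0132; Zmat3, Gadd45a, Bbc3 and Cdkn1a, the last from 92.1 to 27.0 RPKM), each with an adjusted p = 0.754 with an estimated correlation. For the lists without a count given here, 0 members passed adjusted over the list alone. Leaving out X0 ended the calls for TOP factors (0.748), mitotic genes (0.498), DNA replication (0.62), the respiratory chain (0.0915), mitochondrial ribosomal proteins (0.224) and the NIH3T3 total RNA list p53 targets (0.958), and leaving out X4 that for the proteasome (0.102).

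The 2 cell lines were then set side by side. Over 7259 genes measured in both, the occupancy slopes correlated across genes with a Pearson r of 0.534 and a Spearman rho of 0.544, and 70.0% had the same sign. Genes are not independent replicates, and 22 of the 60 orders of the mouse levels, the real one included, gave a correlation as large in size (median 0.457, highest 0.633). Of genes at an unadjusted p under 0.05 in each line, 82 were higher in both where 39.1 would come from independent lists, and 186 lower in both where 108 would. Opposite directions were found for 8 genes higher in human and lower in mouse (46.6 by chance) and 20 the other way round (91.2). In limma's test of the difference between the lines 0 genes passed, with the mouse slope higher for 2193 and lower for 397 at an unadjusted p under 0.05, where 363 would arise by chance. No other tool was run on this difference. By list, 5 of 22 differed: the mouse slope was lower for cytosolic ribosomal proteins (median difference −0.08, adjusted p = 5.81e-09, and adjusted p = 0.851 with an estimated correlation), the respiratory chain (−0.11, adjusted p = 1.57e-09, and adjusted p = 0.148 with an estimated correlation), mitochondrial ribosomal proteins (−0.10, adjusted p = 1.42e-07, and adjusted p = 0.774 with an estimated correlation) and the proteasome (−0.10, adjusted p = 9.31e-06, and adjusted p = 0.774 with an estimated correlation), and higher for cell-surface and secreted proteins (0.20, adjusted p = 0.000709, and adjusted p = 0.851 with an estimated correlation).

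The let-7a libraries asked what mature let-7a does where LIN28B is lowest. Against untransfected X0, let-7 targets had lower total RNA, with a median log2 change of −0.47 over 53 genes and 81.1% of them below the median of all genes. Of 10000 random lists matched on expression, 0% had a median as low, and the central 95% of random medians ran from −0.15 to 0.14. HMGA2 went from 5.87 to 0.737 RPKM (3507 to 389 reads), a log2 change of −2.36. IGF2BP2 stood at −1.45, residual LIN28B at −1.10, IGF2BP1 at −0.94, IGF2BP3 at −0.91, ARID3A at −0.78, TMEM2 at −0.55, CCNB1 at −0.43, DICER1 at −0.35 and NR6A1 at −0.29, while CDK4 (−0.02) and ARID3B (0.00) were close to the median of all genes, 0.00. These are 1 library each from tables normalized separately, so the differences have no replicate check and no test. None of the libraries used here had a control transfection, so let-7a cannot be told apart from the transfection itself, for these and the lists below.

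Other lists also stood apart from random lists in let-7a total RNA. Relative to all genes, glycolysis lay at −0.47 (percentile 0.01), the proteasome at −0.43 (percentile 0), splicing factors at −0.37 (0.03), DNA replication genes at −0.33 (0.18), initiation factors at −0.33 (1.03), the respiratory chain at −0.24 (0.65) and mitochondrial ribosomal proteins at −0.31 (0). ATF4 targets lay at 0.52 (percentile 100), the 6 pluripotency markers at 0.61 (99.7), mitochondrially encoded genes at 0.35 (99.98) and cytosolic ribosomal proteins at 0.17 (99.99). Ribosome occupancy of let-7 targets differed little from that of other genes, with a median of −0.04 relative to all genes (percentile 29.5). The occupancy of cytosolic ribosomal proteins was lower, at −0.68 (percentile 0; central 95% of random medians −0.36 to −0.08), as it was for the respiratory chain (−0.53, percentile 0; −0.35 to −0.06), the proteasome (−0.46, 0.55; −0.40 to 0.03), mitotic genes (−0.45, 0.18; −0.36 to 0.08), the 7 measured histones (−0.49, 0.93; −0.40 to 0.46) and mitochondrial ribosomal proteins (−0.39, 0.02; −0.30 to −0.01). Mitochondrially encoded genes lay at 1.19 (percentile 100; −0.58 to 0.04).

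**Figure D4:**
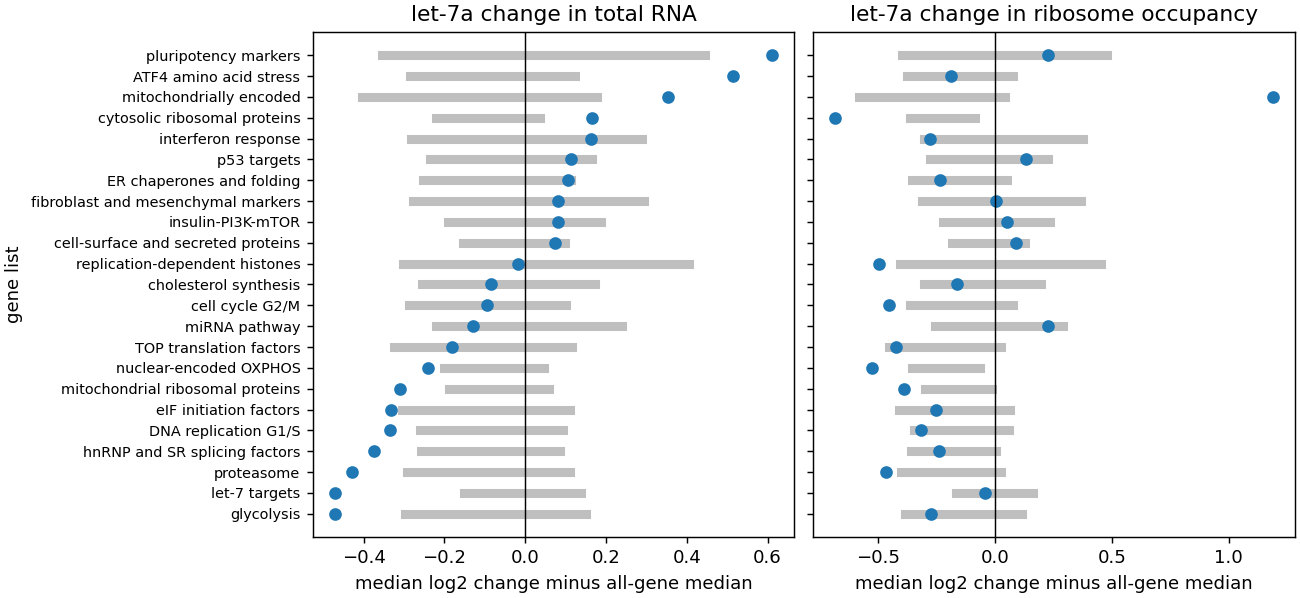
Median log2 change of each gene list between X0 with let-7a and X0 without, minus the median of all genes, for total RNA (left) and ribosome occupancy (right); blue points are the lists, and grey bars the central 95% of medians of 10000 random lists matched on expression. The let-7 targets lie at −0.47 in total RNA and −0.04 in occupancy, from 1 library per condition and fraction.

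Small RNA bound to AGO2 consisted almost wholly of microRNA features, which took 98.1% to 98.5% of counts in the 4 AGO2 libraries and 74.5% to 81.0% in the 4 total libraries. In the knockout without let-7, for example, these shares were 98.4% (exact binomial 95% interval 98.4 to 98.5) and 81.0% (80.7 to 81.2). Mitochondrially encoded features made up 0.201% to 0.313% of the AGO2 counts and 11.3% to 16.9% of the total. In total small RNA the let-7 transfected libraries had a microRNA share of 74.5% (knockout) and 74.9% (X3) against 81.0% and 79.5% without, and a mitochondrial share of 16.9% and 16.3% against 11.3% and 12.1%, without a test at 1 library each. A set of 3 features, hsa-mir-125a, MIR486 and MIR3184, held 97.8% to 98.3% of the AGO2 counts. Which locus and strand the hsa-mir-125a feature covers is not given in the sources used here, and the microRNA gene overlaps SPACA6, so its share and the microRNA shares above are uncertain as measures of this microRNA. MIR3184 lies at the same place as MIR423, which had 0 counts. If reads were counted on the opposite strand, the counts of MIR3184 may belong to MIR423, and the other microRNA shares are uncertain too. MIR486, a microRNA known from red cells and muscle, made up 31.0% ± 3.88 of AGO2 counts and 10.0% ± 1.52 of total counts (SD, n = 4 each), and hsa-mir-125a 55.2% ± 3.09 and 45.4% ± 1.45. Intervals and detection limits here cover counting error only.

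Between the fractions, 83 of 115 tested features differed with edgeR's quasi-likelihood test, 26 higher and 57 lower with AGO2. Among features with a mean of at least 50 counts, MIR486 (log2 ratio 4.85, adjusted p = 3.93e-46) and hsa-mir-125a (3.51, adjusted p = 4.87e-33) were the most enriched, each higher in share in the AGO2 libraries. With microRNA features alone the call for hsa-mir-125a was lost (0.62, adjusted p = 0.0787), and scaled to the library total its ratio was 0.25. MT-CO2 (−4.29, adjusted p = 1.24e-20), MTND5P11 (−4.29), MT-CYB (−3.80), RP5-857K21.11 (−3.80) and RP5-857K21.7 (−3.50) were the most depleted at that mean count, and features with fewer counts had larger ratios both ways. These ratios depend on the scaling, as MT-CO2 made up 0.00639% ± 0.00258 of AGO2 counts and 1.16% ± 0.326 of total counts (SD, n = 4 each), a wider gap than its ratio, and the shares of MIR486 lie closer together than its ratio. MTND5P11 is a nuclear copy of a mitochondrial gene and shares reads with it. The scaling set the direction of some features. MIR3184 was higher by the main normalization (2.40, adjusted p = 1.49e-15, edgeR) but lower when scaled to the library total (−0.86). Its shares were 11.8% with AGO2 and 21.2% in total. RP11-125K10.5 (3.03 and −0.18) and FSD2 (2.36 and −0.88) turned in the same way. Scaled to the library total, 6 features were higher and 101 lower, and with microRNA features alone 6 of 13 differed.

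**Figure D5:**
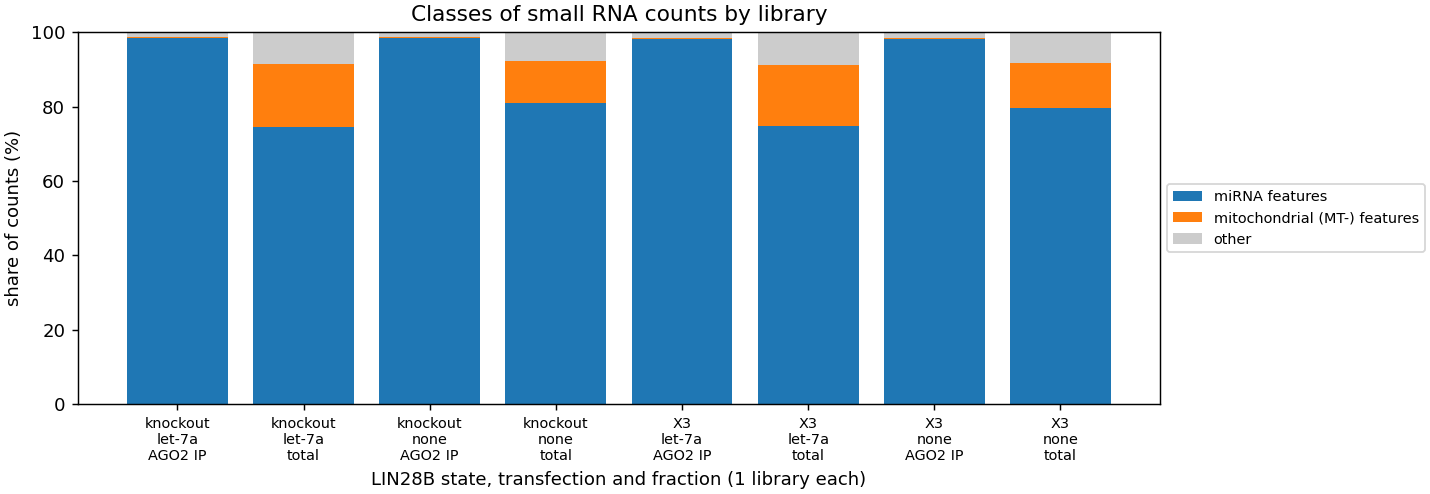
Share of counts (%) on microRNA, mitochondrial (MT-) and other features in the 8 HEK293A small RNA libraries, 1 bar per library. MicroRNA features hold 98.1% to 98.5% of counts with AGO2 and 74.5% to 81.0% in total small RNA.

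The let-7 family was nearly undetected in these counts, which may say little about let-7 levels if reads were counted on the opposite strand. Of its 13 features, 3 had any counts, MIRLET7A1, MIRLET7A2 and MIR98. Transfected libraries held 14 let-7 counts among 396060 (35.3 CPM), namely 5 and 4 in the knockout and 3 and 2 at X3 with AGO2 and in total. Untransfected libraries held 0 of 607335, which allows up to 4.94 CPM. Fisher's exact test on these reads, two-sided, gave p = 2.23e-06, and it compares the libraries rather than the conditions. The knockout and X3 did not differ detectably at this depth (9 against 5 counts in the transfected libraries, Fisher's exact p = 0.594). LIN28B reads numbered 2 in the untransfected X3 total library and 0 in the other 7, so the counts do not check the LIN28B state.

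Few single small RNA features passed for LIN28B or let-7 transfection. For LIN28B, knockout against X3, 0 of 115 features passed with edgeR (6 at an unadjusted p under 0.05) and 0 with DESeq2 (2 unadjusted), and 1 passed without the untransfected X3 AGO2 library. For let-7 transfection 2 passed, 1 up and 1 down (19 at an unadjusted p under 0.05), while DESeq2 called neither of them and 1 other that fell, MIR3184 (−0.40, adjusted p = 0.0235), named after its values were seen. The feature that rose with edgeR, SCN10A, had 28 counts in the transfected libraries and 0 in the others, at least 14.3-fold higher against a floor of 3 counts over the group (adjusted p = 0.000114, edgeR). In the transfected libraries these were 17 (knockout) and 10 (X3) in total small RNA, and 0 and 1 with AGO2. SCN10A has fewer counts than the rule for named features asks and was picked after its values were seen. The feature that fell was CTD-2328D6.1 (−1.29, adjusted p = 0.0275, edgeR; −0.27, adjusted p = 0.905, DESeq2), at 0.0267% ± 0.0294 of counts with let-7 and 0.0693% ± 0.0881 without (SD, n = 4 each), and it did not keep its direction with interaction terms (0.44). Counts for let-7 were 0 without the transfected knockout total library or the transfected X3 total library, 1 without the untransfected X3 total library, 4 without the untransfected X3 AGO2 library, 9 with DESeq2's size factors and 18 when scaled to the library total. With 1 library per combination these tests assume that the factors act additively.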

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

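The tests of explanations by level orders, splits of the libraries, gene length, neighbouring genes, the let-7a comparison, microRNA overlaps and opposite-strand counting had their outcomes for and against set down only after the results were seen.

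Occupancy slopes of 5 lists differed between the lines by camera's test of the difference. NIH3T3 minus HEK293A, the median difference was −0.0762 for cytosolic ribosomal proteins (medians 0.04 and 0.13), −0.11 for the respiratory chain (−0.03 and 0.10), −0.10 for mitochondrial ribosomal proteins (−0.05 and 0.06) and −0.10 for the proteasome (−0.06 and 0.06). It was 0.20 for cell-surface and secreted proteins (−0.06 and −0.24). Across all genes the median slopes were −0.01 in NIH3T3 and −0.07 in HEK293A. None of the 5 held with an estimated correlation.

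The first pattern is the HEK293A occupancy trend. Of the 60 orders of the levels, 2 gave at least as many genes as the real order, itself included (6465, highest other 6878). The order with X1 and X2 exchanged gave more. Few orders do as well, but with 1 library per level this cannot exclude chance differences between libraries that run along the levels. The tables argue against gene length as the whole cause, since 6510 genes passed after the length trend was removed, 6264 of them called before in the same direction. Regional base composition stays open: slopes of adjacent genes correlated at 0.427 across 9527 pairs, against 0.0423 for the highest of 1000 shuffles, and at 0.248 for genes 20 places apart, and no genome sequence was used to test it directly. A difference in polysome library composition and LIN28B itself cannot be told apart with 1 library per level. The correlation of the let-7a change at X0 with the slopes over X1 to X4 (−0.342) may come from let-7a itself or from the transfection.

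The second pattern is the correlation of slopes between the cell lines. Of the 60 orders of the NIH3T3 levels, 22 gave a correlation as large as the real 0.534 (highest other 0.633), so chance cannot be excluded. For the NIH3T3 occupancy trend alone, 19 of 60 orders gave as many genes at an unadjusted p under 0.05 (552, highest other 3418), so chance cannot be excluded there either. An order with several times the real count points to a structure of these libraries other than the level order, and 10 of the 60 orders had genes past the adjusted threshold, up to 1412 in the order X0, X1, X4, X2, X3.

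The third pattern is that 42 of 48 microRNA genes named in advance had 0 counts. Loss of reads where a microRNA gene overlaps another gene and true absence cannot be told apart: the 4 genes without an overlap held 0.00708% of all counts, and 3 of them had 0. Counting on the opposite strand is a candidate explanation, since MIR3184 held 16.3% of all counts while MIR423, which lies at the same place, held 0. If so, the low let-7 counts may say little about let-7 levels, and the shares of microRNA features little about which microRNAs were present. No biological explanation was tested.

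For small RNA, the LIN28B comparison gave 0 features, so any split gives as many (33 of 33) and the number says nothing about chance (highest other 13). The split with 13 points to a structure of these libraries other than LIN28B. For let-7 transfection 6 of 33 splits gave as many as the real 2 (highest other 3), so chance cannot be excluded. For AGO2, 1 of 33 splits, the real one, gave 83 features (highest other 0), and no split can do better than 1 of 33. The other splits were fitted without a term for fraction, so the difference between fractions widened their spread and lowered their counts. The splits therefore do not exclude chance.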

How the results depend on the processing

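Centring and quantile normalization of the list tests, the settings tried on each called list, the let-7a total RNA settings, the small RNA fits without the 3 largest features or on 1 fraction alone, the pairing of total and AGO2 libraries by condition, and the length correction were chosen after seeing the data. No paired analysis was possible for the trends over the LIN28B levels because the labels give no replicate numbers and each level has 1 library. For the same reason a replicate block was not run, and the measured LIN28B value was not run as covariate in NIH3T3, where LIN28B is hardly measured. Of 3619 values for named genes, lists and features under alternatives, 3285 kept their side of the threshold, 287 lost the call, 42 gained one and 5 reversed. A change of direction was counted as reversed only where a call was involved. The 3285 therefore include values without a call that changed direction, such as CDK4 occupancy in HEK293A (−0.06, and 0.01 with the count test). The cause was not tested except where fewer genes or libraries entered. Counts within 1.5 times the reported one are not listed, such as 4821 to 6663 for HEK293A occupancy with other pseudocounts, filters, scales, covariates and the count test. At the depth of the small RNA libraries a count of 0 over the untransfected libraries allows up to 4.94 CPM.

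HEK293A occupancy called 2 genes with X0 against the rest, and 0 to 7231 leaving out 1 level. Its list calls went from 6 to 0 with an estimated correlation and 3 with quantile normalization, of which ATF4 targets were not among the 6. With fry, which tests against no change rather than against other genes, it was 8, of which only cell-surface and secreted proteins were among the 6. The HEK293A spread ratio was 2.19 at a mean of at least 5 RPKM, 2.32 at 20, 2.02 at a pseudocount of 0.1 and 1.69 with X1 as reference (X4 over X2). HEK293A total RNA called 117 genes at a mean of at least 5 RPKM, 159 after centring, 3 with X0 against the rest, and 3 to 544 leaving out 1 level, and its list calls were 0 with an estimated correlation and 0 with fry. NIH3T3 occupancy list calls were 0 with an estimated correlation and 0 with fry, and its spread ratio was 0.952 at 20 RPKM and 0.864 with X1 as reference. NIH3T3 total RNA called 2241 genes with X0, 1 library, against the rest and 0 to 22 leaving out 1 level, with list calls 0 with an estimated correlation and 0 with fry. The correlation of the lines was 0.481 at a mean of at least 5 RPKM and 0.495 with quantile normalization.

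For LIN28B and small RNA, 1 feature passed with DESeq2's size factors, 1 scaled to the library total, 1 without the filter, 1 without the 3 largest features and 2 in AGO2 libraries alone, and 0 to 1 leaving out 1 library. For let-7 the count was 9 with size factors, 18 scaled to the library total, 1 with DESeq2's Wald test (not among the 2), 0 with LIN28B by fraction and let-7 by fraction terms, 1 without the other 2 factors, 1 for microRNA features only, 0 in AGO2 libraries alone, and 0 to 4 leaving out 1 library. For AGO2 it was 6 for microRNA features only, 78 in the paired fit and 69 to 80 leaving out 1 library. Reversed values were CTD-2328D6.1 at 0.44 with the fraction terms, and scaled to the library total RP11-125K10.5 at −0.18, MIR3184 at −0.86 (−0.49 for microRNA features only) and FSD2 at −0.88.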

Other observations

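Some HEK293A lists, picked after their values were seen, held more single genes with lower occupancy than the 4341 of 11125 over all genes (2962 after centring), without a call by camera. Targets of ATF4 had 17 of 28 members down and 2 up (adjusted over the list alone 17 and 2; 12 and 4 after centring; camera's adjusted p = 0.0905, 0.0452 with quantile normalization, and 0.736 with an estimated correlation). Glycolysis had 15 of 23 down and 4 up (15 and 4 adjusted over the list alone; 13 and 6 after centring; adjusted p = 0.193, and 0.757 with an estimated correlation). Targets of p53 had 12 of 23 down and 5 up (13 and 5 adjusted over the list alone; 10 and 5 after centring; adjusted p = 0.415, and 0.736 with an estimated correlation). Genes of the insulin, PI3K and mTOR pathway had 13 of 26 down and 2 up (13 and 2 adjusted over the list alone; 9 and 5 after centring; adjusted p = 0.415, and 0.736 with an estimated correlation). By contrast, genes of the microRNA pathway had 7 of 18 down and 1 up (7 and 1 adjusted over the list alone; 3 and 2 after centring; adjusted p = 0.405, and 0.736 with an estimated correlation), about the share of all genes.

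The first principal component of HEK293A occupancy held 80.8% of the variance and placed X0 at −43.6, X1 at −9.71, X2 at −17.1, X3 at 26.0 and X4 at 44.4, so that X1 lay nearer to X3 and X4 than X2 did.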
